A study of Homo sapiens with 6 samples.

How the data were processed

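IGROV-1 cells were cultured with ascites of mice treated with saline or with CpG oligodeoxynucleotide, and total RNA was profiled on 6 Illumina bead arrays, 3 per group. Per the labels' protocols, RNA was extracted with Trizol and cleaned on columns with DNase treatment, and biotinylated cRNA was made with an Ambion amplification kit. Samples were assigned to groups from the treatment given in the labels, and to replicates from their titles. Per the labels, mice received the oligodeoxynucleotide once or on consecutive days; which schedule each ascites came from, and whether ascites was pooled, are not given in the sources used here.

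Per the submitters' processing notes, the arrays were summarised with BeadStudio, whose version is not given in the sources used here. The deposited table of probe intensity was not normalized, per the file headers, and its values show no background subtraction. Per the file headers, it also holds a detection p-value for each probe on each array. A second deposited table gives the authors' processed intensity for 48803 probes, 2 more than the first. On each array its ranks equal those of the non-normalized values (Spearman correlation of 1), its medians are 121 on every array, and its quantiles nearly coincide. It is therefore on a linear scale, as if quantile normalized without background subtraction; the authors' method for it is not given in the sources used here. It was used as an alternative. All columns of per-sample values were used.

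Background was corrected and intensities were normalized with the neqc function of limma 3.58.1 in R 4.3.3. It fits a normal and exponential mixture with the negative control mean and SD inferred from the detection p-values, adds an offset of 16, applies quantile normalization and takes log2. Probes with a detection p-value under 0.01 on at least 3 of the 6 arrays, whatever their group, were kept. Gene names came from the platform annotation of the probes: 28097 probes had 1 gene symbol, 13 had several and 20691 had none, and none was named from a probe with several. Symbols were looked up by gene number in a reference gene table, which held 28059 of the named probes. Of the 13713 probes kept, 11833 had 1 symbol. One probe per gene, that with the highest mean log2 intensity, stood for the gene in lists and in the genes named by the rule below, while counts and calls of probes cover all probes kept.

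Groups were compared with lmFit and eBayes of limma, with no covariate, as CpG ascites minus saline ascites, two-sided. P-values were adjusted by Benjamini and Hochberg over all probes kept, with a threshold of 0.05. Values after ± are the standard error of the fitted log2 change where marked SE, and the SD over 3 arrays where marked SD. A probe above background on no array of 1 group has only a bound, computed as the other group's mean against the mean of, per array, the higher of the lowest detected signal and the probe's own value. Gene lists fixed before the data were examined were tested where at least 5 genes were measured. The test was camera with a preset correlation of 0.01, with an estimated correlation and the fry tests as alternatives, and adjusted p-values cover all 32 lists. DNA repair was chosen for a comparison of its own before the data were examined, from prior knowledge of the study; the labels do not name it.

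The genes to be named were also fixed before the data were examined. They are the 10 genes in each direction with the largest change among those past the threshold without overlap of the groups, or with the smallest p where fewer passed. From each list they are up to 4 genes past the threshold, or up to 2 with the smallest p, and from DNA repair up to 10, or 6 with the smallest p. TLR9 and other probes of the named genes complete the rule. Genes that passed over a called list alone, and genes described as singled out, were added after their values were seen.

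The fits were tested on simulated data drawn from the real probe means and SDs within groups, for the comparison of CpG with saline ascites over 13713 probes. Probes were drawn independently, with no correlation between genes and no outlying array, so these results may not carry over to the real arrays. Of 100 probes changed by a log2 of 1, 53.0% were recovered, and of 100 changed by a log2 of 2, 91.0%, with 10 false calls. Without CpG ascites replicate 1 the shares were 63.0% and 92.0%, with 8 false calls. In the simulation a list shifted by -0.3 passed camera with an adjusted p of 0.00184, but had an adjusted p of 0.514 with an estimated correlation.

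Alternatives were another background correction (normexp with an offset of 50), none, median scaling, the authors' values, other probe filters, a mean-variance trend, array weights, the replicate number as a block, each array left out, a plain two-sample test, a minimum log2 change of 1 and the mean of all probes of a gene. The array position on a chip was planned as a block but is not given in the column names, so that alternative was not run.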

Results

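The series measured gene expression in IGROV-1, an established human ovarian carcinoma cell line, after culture in medium mixed with an equal volume of mouse ascites for 24 h. The ascites came from mice that carried IGROV-1 tumours in the peritoneum. The mice had received either saline or CpG oligodeoxynucleotide at 20 µg per mouse, a synthetic DNA that activates Toll-like receptor 9. RNA of 3 samples with saline ascites and 3 samples with CpG ascites was hybridised to 1-colour Illumina bead arrays with 48801 probes. Mean probe intensity ranged from 587 to 788 per array, and between 13303 and 13835 probes per array lay above background. A total of 13713 probes were kept, which named 9211 genes. The number of arrays, 3 per group, limits the precision of every value. There were 3 mice per group, but the labels do not say whether the 3 samples of a group came from separate animals or cultures. P-values therefore measure only the spread between these samples, which may be technical.

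CpG ascites replicate 1 lay apart from the other 5 arrays. Its Pearson correlation with the others, across probes, was 0.948 to 0.958, while the other 5 arrays correlated with each other at 0.978 to 0.992. On this array 189 probes lay more than 4-fold below the saline mean and 0 lay more than 4-fold above it, against 1 probe below on CpG ascites replicate 3 and 0 on replicate 2. The keratin gene KRT18 had a log2 intensity of 4.75 on that array and between 7.03 and 7.71 on the others, and 5.29 against 7.08 to 7.57 on its second probe. The interferon-induced gene IFIT3 had 5.77 against 8.44 to 9.30, but 7.46 against 7.45 to 7.92 on its second probe. Both genes were singled out after their values were seen. The counts of probes and the calls of gene lists are given with and without CpG ascites replicate 1. The remaining CpG arrays were not alike either. Changes against the saline mean correlated across probes at 0.44 between CpG ascites replicates 2 and 3. With replicate 1 they correlated at 0.33 for replicate 2 and 0.20 for replicate 3. Array weights were 0.27, 1.07 and 0.61 for CpG ascites replicates 1, 2 and 3, and 1.58 to 1.95 for the saline arrays.

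**Figure D1:**
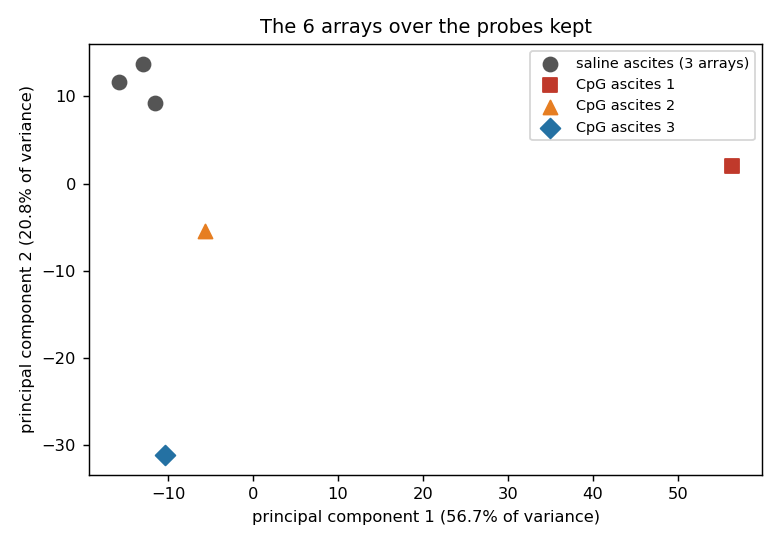
Each point is 1 of the 6 arrays, placed on the first principal component (horizontal axis, 56.7% of the variance) and the second (vertical axis, 20.8%) of log2 intensity over the 13713 probes kept. CpG ascites replicate 1 lies at 56.3 on the first component, and the other 5 arrays lie between -15.7 and -5.67. On the second component CpG ascites replicate 3 lies at -31.2, and the other 5 arrays lie between -5.4 and 13.8.

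The first comparison asked which genes differed between tumour cells exposed to CpG ascites and cells exposed to saline ascites. The gene with the smallest p was PPIB, which encodes cyclophilin B, a protein-folding enzyme of the endoplasmic reticulum, with a log2 intensity of 11.13 ± 0.10 (SD) in saline ascites and 9.69 ± 0.23 in CpG ascites. SNRPE, a core protein of the spliceosome, was at 8.89 ± 0.11 and 7.76 ± 0.15. On the other side, the epithelial transcription factor EHF was at 6.65 ± 0.37 in saline ascites and 7.80 ± 0.23 in CpG ascites, and RGS14, a regulator of G protein signalling, at 7.03 ± 0.15 and 7.95 ± 0.08. EHF was not above background on every array. In all 4 genes the 3 CpG arrays lay on one side of the 3 saline arrays, but none of the 4 passed the test over all probes.

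With limma and Benjamini-Hochberg adjustment, 0 probes were higher and 0 were lower in CpG ascites, and the smallest adjusted p was 0.116. At an unadjusted p under 0.05 there were 941 higher and 818 lower probes, a total of 1759 where chance alone gives 686. A plain two-sample test of each probe also gave 0 probes after adjustment, with 810 higher and 770 lower at an unadjusted p under 0.05. The 2 groups did not overlap at 2837 probes, which is 20.7% of those kept, where chance gives 10%. Of these, 1490 were higher and 1347 lower in CpG ascites.

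The 10 genes with the smallest p in each direction are given as values without a call. Among those with higher values, FBRSL1 had a log2 change of 1.16 ± 0.16 (SE), EHF 1.16 ± 0.21, RGS14 0.92 ± 0.13 and the sulfotransferase gene SULT1C2 0.87 ± 0.16. FBRSL1 and EHF were not above background on every array, so the size of their changes is less certain. Over the settings run for named probes, these changes ran from 0.69 to 1.29 and from 0.70 to 1.29. The transporter gene SLC4A11 had 0.75 ± 0.14, LEMD1 0.75 ± 0.13 and PAQR6 0.74 ± 0.12. CPA4, a carboxypeptidase gene, and HES2, a basic helix-loop-helix repressor gene, were not above background on any saline array, so their CpG level was at least 1.98-fold and at least 1.17-fold higher. GAS6, the ligand of the AXL receptor family, was likewise at background in saline ascites, with a log2 intensity of 5.68 against 6.63, a bound of at least 1.00-fold. The adjusted p of these 10 genes ran from 0.116 for GAS6 to 0.157 for EHF.

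Among those with lower values, PPIB had a log2 change of -1.44 ± 0.15 (SE), the DNA sensor gene CGAS -1.17 ± 0.19, SNRPE -1.13 ± 0.14 and CAPZA1, a subunit of the actin capping protein, -1.07 ± 0.16. CGAS was not above background on every array, and its change ran from -1.32 to -0.74 over the settings run for named probes. NME2, a nucleoside diphosphate kinase gene, had -0.92 ± 0.15 on its most intense probe, but -0.13 ± 0.13 and -0.45 ± 0.19 on its other probes. RANGRF had -0.89 ± 0.13, CYP51A1 of cholesterol synthesis -0.77 ± 0.13, and PMAIP1, the pro-apoptotic NOXA gene, -0.74 ± 0.12. FCGR3B and C1D were above background in saline ascites and on no CpG array, at least 1.5-fold and at least 1.59-fold lower. The adjusted p ran from 0.116 for PPIB to 0.136 for C1D. Second probes of PAQR6, SULT1C2 and PMAIP1 had log2 changes of 0.45 ± 0.14, 0.78 ± 0.22 and -0.55 ± 0.19.

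**Figure D2:**
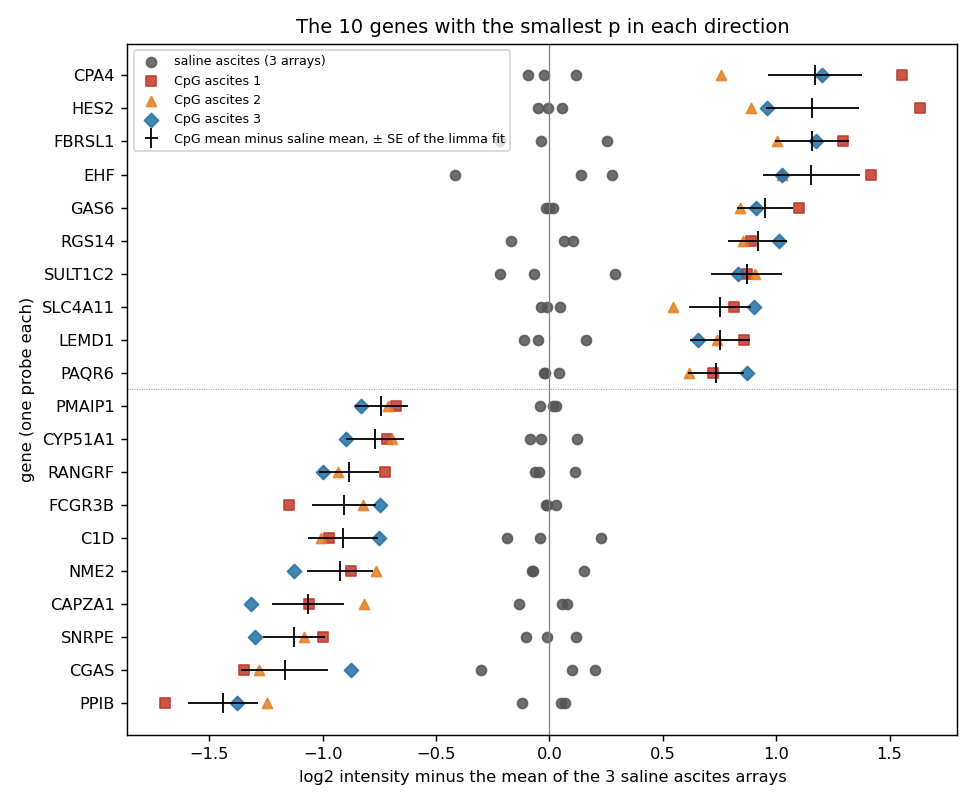
Each row is 1 gene and each point 1 array, placed by its log2 intensity minus the mean of the 3 saline ascites arrays; the black mark is the difference of the group means with its SE from the limma fit. In all 20 genes the 3 CpG ascites arrays lie on one side of the 3 saline ascites arrays. CPA4, HES2 and GAS6 were at background in saline ascites and FCGR3B and C1D in CpG ascites, so their marks show no exact change. FBRSL1, EHF and CGAS were not above background on every array.

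Without CpG ascites replicate 1, 3 probes were higher and 18 lower at an adjusted p under 0.05 in limma, with 935 higher and 1105 lower at an unadjusted p under 0.05. The 3 higher genes were CFB, complement factor B (log2 change 1.00 ± 0.13, SE), GRIPAP1 (1.07 ± 0.13) and HES2. The bound given above for HES2 is over all 6 arrays. Its log2 intensity was 7.33 on CpG ascites replicate 1 against 6.58 and 6.65 on the other CpG arrays. That bound therefore leans on replicate 1, and none is given without it. The 11 lower genes were PPIB (-1.31 ± 0.13), SNRPE (-1.19 ± 0.14), RANGRF (-0.97 ± 0.13), the chromatin protein gene HMGB1 (-1.48 ± 0.17), the heat shock gene HSPA1B (-1.03 ± 0.13), the Mediator gene MED21 (-1.36 ± 0.16), the proteasome gene PSMC6 (-1.22 ± 0.16), TSN (-1.26 ± 0.16), COPS2, DDHD1 and NAP1L1. The last 3 were not above background on any CpG array at these probes, and over all 6 arrays they were at least 1.96-fold, 1.49-fold and 1.45-fold lower. The probes of HMGB1, PSMC6, COPS2, NAP1L1 and GRIPAP1 that passed were not the brightest of their genes on average. The brightest, without this array, had log2 changes of 0.01 ± 0.13, -0.29 ± 0.13, -0.55 ± 0.14, -0.39 ± 0.17 and 0.11 ± 0.22, and none of these passed. The other 7 lower probes had no gene name here, and genes outside the first 20 were singled out because they passed this test. The adjusted p of the 21 probes ran from 0.0486 to 0.0490.

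The next comparison asked whether genes of DNA repair differed between the groups. TDP2, which removes trapped topoisomerase from DNA ends, had a log2 change of -0.97 ± 0.17 (SE) in CpG ascites, and the base excision glycosylase gene NEIL2 had 0.86 ± 0.19. The DNA polymerase delta subunit gene POLD3 had 0.68 ± 0.16, RMI1 of the complex that dissolves recombination junctions -0.60 ± 0.14, and CCNH, a subunit of the kinase of transcription factor TFIIH, -0.49 ± 0.12. The checkpoint mediator gene CLSPN was above background in saline ascites and on no CpG array, at least 1.2-fold lower. These 6 had the smallest p of the 124 repair genes measured, and none passed the test over all probes, with adjusted p from 0.153 for TDP2 to 0.218 for CCNH. Other probes of TDP2, CCNH and RMI1 had -0.70 ± 0.20, -0.21 ± 0.13 and -0.19 ± 0.14.

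Of the 124 repair genes, 68 had higher and 56 had lower values in CpG ascites, and 9 and 11 of them had an unadjusted p under 0.05. Over all 13713 probes kept, 941 higher and 818 lower had such a p. After adjustment 0 passed over all probes and 0 adjusted over the list alone. The median log2 change of the list was 0.03 and its mean -0.00389, opposite in sign. With 1 array left out the median ran from 0.0017 (without CpG ascites replicate 2) to 0.049 (without CpG ascites replicate 3), so its size is not settled. The camera test of limma, which compares a list with all other genes, gave an adjusted p of 0.973, or 0.751 without CpG ascites replicate 1. The mixed fry test, which asks whether members differ in either direction and does not compare them with other genes, gave an adjusted p of 0.0264. It passed 13 of the 32 lists, among them parts of repair and lists outside repair, so this is not particular to repair.

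The parts of repair were tested as lists of their own, and none passed camera. In the mixed fry test, mismatch repair (adjusted p 0.00182), damage signalling (0.0050) and nucleotide excision repair (0.0197) passed. Base excision repair (0.124), homologous recombination (0.299) and end joining (0.560) did not. That test gives no direction and does not compare members with other genes. Values in parentheses after a median are the lowest and highest with 1 array left out. Mismatch repair (18 genes) had a median log2 change of -0.09 (-0.10 to 0.04), with LIG1, the replicative DNA ligase gene, at 0.45 ± 0.13 (SE). Homologous recombination with the Fanconi anaemia genes (30 genes) had -0.02 (-0.07 to 0.0074), with FANCI at -0.43 ± 0.12. Both medians turned without CpG ascites replicate 1 and with the mean of all probes of a gene, so these lists have no settled direction. Nucleotide excision repair (22 genes) had 0.08 (0.04 to 0.10), with UVSSA at 0.40 ± 0.12, and base excision repair (23 genes) had 0.06 (0.05 to 0.09), with the DNA polymerase epsilon gene POLE at 0.49 ± 0.19. End joining (8 genes) had -0.05 (-0.05 to 0.06), with LIG4 at -0.40 ± 0.15 and XRCC6, the Ku70 gene, at 0.26 ± 0.16, although second probes had 0.21 ± 0.16 and 0.04 ± 0.14. Its median also turned with the mean of all probes, to 0.04. The list of damage signalling and translesion synthesis (23 genes) had 0.08 (0.02 to 0.10). The camera adjusted p of these 6 lists ran from 0.703 to 0.973. Adjusted over the list alone, 1 base excision gene was higher (NEIL2), and in damage signalling 1 was higher (the checkpoint kinase gene CHEK2, 0.46 ± 0.12, named because it passed) and 2 were lower (TDP2 and CLSPN).

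The third comparison asked which other programmes differed, over 32 lists fixed before the data were examined. Heat shock genes, which encode chaperones, were lower as a list in CpG ascites by camera with a preset correlation (adjusted p 0.00186), but not with an estimated correlation (adjusted p = 0.774). Their median log2 change was -0.25 over 15 genes, with 13 of the 15 below the saline mean and 0 past the test over all probes. HSPA1B, an inducible HSP70 gene, had -0.79 ± 0.21 (SE) and the HSP90 cochaperone gene CHORDC1 -0.65 ± 0.14, and both passed when adjusted over the list alone. HSPA8 had -0.40 ± 0.16 and HSP90AB1 0.27 ± 0.15, and neither passed. When CpG ascites replicate 1 was left out, the median was -0.28, the adjusted p 6.08e-05, and 5 genes passed over the list alone.

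Genes induced by type I interferon were also lower as a list, with a median log2 change of -0.14 and a mean of -0.28 over 29 genes. The camera adjusted p was 0.00219 with the preset correlation, but the call was lost with an estimated correlation (adjusted p = 0.774). The median was -0.083 without CpG ascites replicate 3 and -0.066 with no filter on dim probes. The mean deviation of the list was 0.29 on saline ascites replicate 1, against 0.11 and 0.01 on the other saline arrays, and without that array the camera adjusted p was 0.0331. Adjusted over the list alone, 8 of the 29 were lower and 0 higher. The RNA sensor gene IFIH1 had -0.84 ± 0.25 (SE), the antiviral genes HERC5 and IFI27 -0.68 ± 0.16 and -0.75 ± 0.21, and IFIT1, IFIT2 and IFI6 had -0.60 ± 0.17, -0.52 ± 0.15 and -0.58 ± 0.16. RSAD2, the viperin gene, and OAS2 were on no CpG array above background, at least 1.41-fold and at least 1.38-fold lower. Other members were close to the saline level, among them ISG15 at 0.13 ± 0.19 and MX1 at -0.02 ± 0.19. Without CpG ascites replicate 1 the camera adjusted p was 0.00128 and the median -0.17, but 0 of the 29 genes passed over the list alone, and over probes detected on all 6 arrays the camera adjusted p was 0.0579.

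Genes of the NF-kB and TNF response were higher as a list, with a median log2 change of 0.37 and a mean of 0.21 over 27 genes. The median was 0.24 with the authors' values and with no background correction. It was 0.28 with normexp and an offset of 50. The list still passed camera in these settings, but the size depends on the background correction. The camera adjusted p was 0.0196 with the preset correlation, but the call was lost with an estimated correlation (adjusted p = 0.774). Adjusted over the list alone, 6 were higher and 2 lower. CFB, complement factor B, had 1.29 ± 0.24 (SE), the lymphotoxin beta gene LTB 0.68 ± 0.15, TNFAIP3, a feedback inhibitor of NF-kB, 0.66 ± 0.20, the mitochondrial superoxide dismutase gene SOD2 0.49 ± 0.14, TNF 0.43 ± 0.13 and the chemokine gene CXCL2 0.43 ± 0.13. TNF was not above background on every array, and its change ran from 0.24 to 0.48 over the settings run for named probes. The 2 lower genes were IL1A, the cytokine interleukin-1 alpha, at -1.05 ± 0.21, and BIRC2, an inhibitor of apoptosis, at -0.49 ± 0.15, although a second BIRC2 probe had 0.08 ± 0.14. CXCL8, the interleukin-8 gene, had 0.00 ± 0.17. The camera adjusted p was 0.00678 without CpG ascites replicate 1, where 4 genes were higher and 1 lower over the list alone and the median was 0.26. The call was lost without CpG ascites replicate 3 (adjusted p 0.344) although the median stayed at 0.37, and without saline ascites replicate 3 (0.0529) with a median of 0.31. It was also lost with no filter on dim probes (0.134), where the median was 0.12, and over probes detected on all 6 arrays (0.0579), where it was 0.32.

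**Figure D3:**
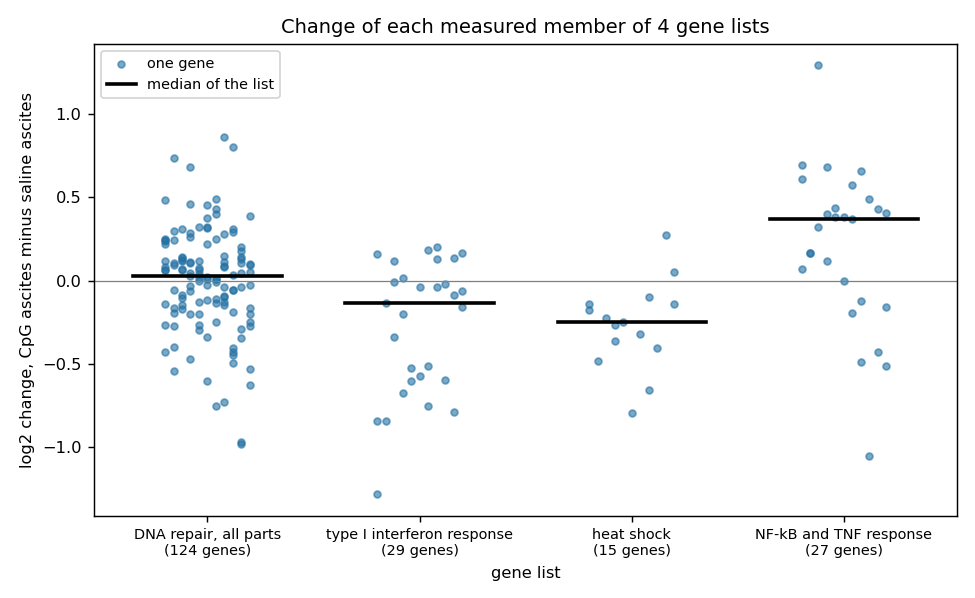
Each point is 1 gene of a list and the black line the list's median, on a vertical axis of log2 change in CpG ascites minus saline ascites. The medians are 0.03 for DNA repair, -0.14 for the type I interferon response, -0.25 for heat shock and 0.37 for the NF-kB and TNF response, and members lie on both sides of 0 in each list.

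For these 3 lists, the mean over members lay on one side in all 3 CpG arrays, and an exact two-sided permutation test of the array means gave p = 0.1, the smallest that 3 against 3 arrays can give. This held for 6 of the 32 lists, where chance gives 10%; the other 3, STAT3 and IL-6, TGF-beta, and WNT, Notch and Hedgehog, did not pass camera, so the separation is not particular to the called lists. With an estimated correlation, 0 of the 32 lists passed camera. The estimated correlation was 0.110 for heat shock, 0.107 for interferon and -0.0042 for NF-kB. The last is below the preset 0.01, so a higher correlation among members was not what removed the NF-kB call. In the simulation this test also missed a list shifted by -0.3, so a loss in it does not by itself show that a list is unchanged. The directional fry test, which asks whether members differ one way on balance, passed 0 lists, with adjusted p of 0.131 for heat shock and for NF-kB and 0.206 for the interferon list. With CpG ascites replicate 1 left out, heat shock passed the directional fry test with an adjusted p of 0.0342, while with an estimated correlation camera still gave 0.469 for heat shock, 0.652 for NF-kB and 0.814 for interferon.

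The remaining lists did not pass camera, with adjusted p from 0.278 to 0.973. Adjusted over the list alone, AXIN2 of the WNT list was higher, and CYP51A1 of cholesterol synthesis and PMAIP1 of the apoptosis list were lower. AXIN2 no longer passed without CpG ascites replicate 1, and BID of the apoptosis list (log2 change -0.54), KDM3A of the hypoxia list (-0.77) and ACSL1 of fatty acid synthesis (-0.51) passed as lower; BID and KDM3A are named because they passed. Of the 29 lists that did not pass, 28 had a median that moved more than 1.5 times with some array left out and 14 had one that changed sign, so sizes and many directions below are not settled; ranges are given as above. Among signalling programmes, the interferon gamma and antigen presentation list had a median log2 change of 0.14 (0.03 to 0.16, and -0.0060 with no filter on dim probes), with HLA-B at 0.52 ± 0.19 (SE) and the immunoproteasome gene PSMB10 at 0.35 ± 0.11. The STAT3 and IL-6 list had 0.08 (0.04 to 0.20), with the acute phase genes LBP and SERPINA1 at 0.58 ± 0.19 and 0.43 ± 0.15. Immediate early genes had -0.09 (-0.11 to 0.02), with FOSB at -0.63 ± 0.17, and TGF-beta targets had -0.03 (-0.09 to -0.04). WNT, Notch and Hedgehog targets had 0.06 (0.04 to 0.25), where AXIN2, a feedback inhibitor of WNT signalling, was at background on the saline arrays and at least 1.15-fold higher in CpG ascites. Its log2 intensity was 7.01, 6.61 and 6.86 on CpG ascites replicates 1, 2 and 3, so this bound leans partly on replicate 1. The Toll-like receptor pathway, with 8 genes measured, had 0.09 (-0.02 to 0.16). The 1 probe of TLR9, the receptor of CpG DNA, was above background on 0 arrays.

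Among metabolic and stress lists, cholesterol biosynthesis had a median of 0.10 (-0.05 to 0.18), with CYP51A1 at -0.77 ± 0.13 and SC5D at -0.46 ± 0.13 (SE). Fatty acid synthesis had 0.00 (-0.10 to 0.13), with the regulator SREBF1 at 0.54 ± 0.18, although its other probe had -0.06 ± 0.25. Lipid oxidation had -0.11 (-0.15 to -0.0077), hypoxia 0.08 (-0.02 to 0.13), glycolysis 0.06 (0.03 to 0.13) and oxidative phosphorylation 0.06 (0.03 to 0.06). The amino acid response had -0.02 (-0.07 to -0.03), the unfolded protein response -0.08 (-0.12 to -0.01) and the oxidative stress and iron list -0.01 (-0.09 to 0.01). The hypoxia list held HK2, the hexokinase 2 gene, at -0.43 ± 0.12, with -0.09 ± 0.24 on its second probe, and NDRG1 at 0.45 ± 0.16.

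In lists of growth and survival, targets of p53 had a median of -0.02 (-0.06 to 0.02), with PPM1D, a phosphatase that turns p53 signalling off, at -0.49 ± 0.16. XPC of the same list had 0.31 ± 0.11. Genes of DNA replication had 0.04 (0.02 to 0.11), with the helicase gene MCM2 at 0.45 ± 0.13. SLBP of that list had -0.50 ± 0.15, although its second probe had 0.02 ± 0.14. Genes of mitosis had -0.01 (-0.05 to 0.03), with ECT2 at -0.43 ± 0.15 and CDC25B at 0.60 ± 0.23. Apoptosis regulators had -0.05 (-0.09 to 0.02), and ribosomal protein genes -0.02 (-0.03 to 0.0073), with RPL7 at -0.44 ± 0.12 and RPL4 at 0.42 ± 0.15. Epithelial genes had 0.04 (-0.00045 to 0.13) and mesenchymal and matrix genes 0.09 (0.03 to 0.19, and -0.04 with no filter on dim probes). The median and mean differed in sign for the lists of fatty acid synthesis (0.00493 and -0.00238), mitosis (-0.00841 and 0.00572), ribosomal proteins (-0.0204 and 0.00258) and damage signalling (0.0769 and -0.0247). Camera takes its direction from the test statistics of the members against those of all other genes, not from either value. That direction had the sign of the mean for fatty acid synthesis and of the median for the other 3 and for DNA repair as a whole.

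Markers of other cell types were too few above background for a list test. Of the lists of myeloid, lymphoid, erythroid and stromal markers, 2, 1, 1 and 3 genes were measured. CD68 and S100A9 of the myeloid list, which holds macrophage and neutrophil markers, had log2 changes of 0.03 ± 0.13 and 0.25 ± 0.22 (SE). The B cell gene CD79B had 0.17 ± 0.16. The alpha globin gene HBA2 was at a log2 intensity of 13.12 in saline ascites and 13.07 in CpG ascites, a change of -0.05 ± 0.17, and its second probe had 0.30 ± 0.16. It was the 1 gene measured of the 10 erythroid markers on the array, and cross-hybridisation to another transcript was not checked, so its level is not read as globin expression. Among stromal markers, PDGFRA had 0.24 ± 0.25, UPK3B -0.51 ± 0.33 and VWF, the von Willebrand factor gene, -0.83 ± 0.19; none passed over all probes, and VWF was lower when adjusted over the list alone. Of the metallothionein list 3 genes were measured, with MT1X at 0.36 ± 0.16, MT2A at -0.06 ± 0.21 and the zinc exporter gene SLC30A1 at 0.24 ± 0.14.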

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

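Alternatives for DNA repair and the counts of probes were planned; those for the 3 called lists and the number of lists were chosen after seeing the data, apart from the estimated correlation, the fry tests and the replicate block. The count of 0 higher probes held in all settings except without CpG ascites replicate 1, and left-out arrays gave 0 to 3 higher and 0 to 18 lower probes. The number of lower probes was 1 (PPIB) with no background correction and with the authors' values, and 14 with a mean-variance trend, 7 of them shared with the 18. The cause was not tested. The number of lists was 1 over probes detected on all 6 arrays, 0 with an estimated correlation and in the directional fry test, and 13 in the mixed fry test. The NF-kB median was 0.12 with no filter on dim probes (adjusted p 0.134) and 0.32 over probes detected on all 6 arrays (0.0579), where the interferon median was -0.076 (0.0579); both filters change which genes are tested. Left-out arrays gave NF-kB medians of 0.26 to 0.37, with adjusted p from 0.00678 to 0.344, interferon medians of -0.18 to -0.083 (the latter without CpG ascites replicate 3), with adjusted p from 7.56e-05 to 0.0331, and heat shock medians of -0.28 to -0.18. The interferon median was -0.066 with no filter on dim probes (0.00217). The NF-kB median was 0.24 with no background correction and with the authors' values, and 0.28 with normexp and an offset of 50, with the call kept. Of the 29 lists that did not pass, 16 had a median that changed sign in at least 1 setting, 7 of them without CpG ascites replicate 1. With an estimated correlation and in the directional fry test, the medians of 0.37, -0.25 and -0.14 were those of the main test, with adjusted p of 0.774 for each in the former and 0.131, 0.131 and 0.206 in the latter. The DNA repair median ran from 0.0017 to 0.055 over all settings, and was 0.030 with an adjusted p of 0.0264 in the mixed fry test, and no other setting passed that list. Heat shock kept its call in all other settings. With the replicate number as a block, 0 probes and 3 lists passed. Deviations of same-numbered samples from their group means correlated at -0.10, 0.01 and -0.02, and 0 of the 6 arrays correlated best with their own number. These values show no pairing by number. They cannot exclude it, because the deviations are from means of 3 arrays and the CpG means include the outlying CpG ascites replicate 1. In the 15 settings run for named probes, 1459 values kept their side of the threshold and 20 newly passed, 14 of them without CpG ascites replicate 1. No named probe passed in the main fit, so keeping its side could only mean not passing. Some of the 14 were followed because they passed without that array, so these counts do not measure stability. Over probes detected on all 6 arrays only 79 of the 100 named probes had a value. Among those without one, FBRSL1, EHF, CGAS, MMP1, TNF, FOSB and LIG4 are given exact changes above, whose size is less certain for that reason. The plain two-sample test, the minimum change and the mean of all probes were not run for the named probes. A block for the array position was not run. Probes near background are limited by their signal: the median intensity of detected probes was 5.86 to 7.86 times background.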

Other observations

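The tests of the list calls, the share of partner probes and the counts of other splits of the arrays for probes were chosen after the results were seen; the tests of correlation and spread on the outlying array, of second probes and of the number of lists were written before.

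Within the epithelial list, which did not pass camera (adjusted p 0.278), 2 of 11 genes were higher when adjusted over the list alone. These were ELF3, an epithelial ETS transcription factor, with a log2 change of 0.80 ± 0.16 (SE), and the mucin gene MUC1 with 0.67 ± 0.16 and 0.81 ± 0.27 on a second probe. EHF, a relative of ELF3, was among the 10 higher genes named first. The cadherin gene CDH1 was not above background on any saline array, so over all 6 arrays its CpG level was at least 1.49-fold higher. Its log2 intensity was 7.96 on CpG ascites replicate 1 and 7.05 and 6.59 on the other CpG arrays, so this bound leans on replicate 1. The claudin gene CLDN7 had 0.50 ± 0.17, and neither gene passed. Without CpG ascites replicate 1 the list's median was 0.12 in place of 0.04, and 4 genes were higher over the list alone, CDH1 and CLDN7 among them. Over all arrays, 7 of the 11 members had higher and 4 had lower values in CpG ascites. The mean deviation of the list was -0.10 on CpG ascites replicate 1, within the saline range of -0.12 to -0.05, against 0.18 and 0.14 on the other CpG arrays. The exact permutation test of the array means gave p = 0.3. KRT18, low on replicate 1 as given above, is a member. The defensin gene DEFB1 had 1.05 ± 0.21 (adjusted p 0.171), and was singled out after its values were seen. In the matrix list the collagenase gene MMP1 had -0.76 ± 0.15 and was the 1 lower gene adjusted over the list alone, while the basement membrane collagen gene COL4A2 had 0.41 ± 0.12. MMP1 was not above background on every array, and its change ran from -0.89 to -0.42 over the settings run for named probes. Without CpG ascites replicate 1, MMP1 was again lower, and COL4A2 (log2 change 0.46) and the urokinase receptor gene PLAUR (0.67, named because it passed) were higher over the list alone.

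On CpG ascites replicate 1, 697 probes lay more than 2-fold below the saline mean and 243 more than 2-fold above it, against at most 183 and 31 on the other arrays. One probe of the actin gene ACTG1 was at a log2 intensity of 5.91 on that array and between 12.76 and 13.28 on the others, while a brighter ACTG1 probe was at 15.62 against 15.28 to 15.45; the gene was singled out after its values were seen. The tables argue against low signal over background as the cause, because among the brightest 25% of probes the SD of its changes was still 1.70 times that of the next CpG array. Failure of single probes in labelling or hybridisation stays open: 2 probes of a gene correlated across 2200 genes at 0.3002 on this array, against 0.291 and 0.329 on the others, and genes are not independent replicates. Of 70 probes that lay 4-fold below the saline mean and had a partner probe, 32.9% of partners were 2-fold below, against 5.91% of all such probes, and both KRT18 probes were low on this array, so the falls may be partly shared by the gene's other probe, and no biological explanation was tested.

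The 3 list calls were weighed against CpG ascites replicate 1 and against differences between ascites samples that have nothing to do with treatment. That array alone does not account for them, since without it the camera adjusted p was 0.00678 for NF-kB, 6.08e-05 for heat shock and 0.00128 for the interferon list. With an estimated correlation these were 0.652, 0.469 and 0.814, so this holds for the preset correlation. The gap in list mean between the nearest arrays of opposite groups was taken against the larger range within a group. It was 0.906 times that range for NF-kB, 0.505 for heat shock and 0.305 for interferon. The array means of the groups therefore did not overlap, but this nearest gap was smaller than the range within a group. Differences between ascites samples therefore cannot be told apart from the treatment with 3 arrays a group, and the treatment stays open and untested beyond this comparison. The real split gave 3 lists and the highest of the other splits 2; 1 of the 10 splits reached 3, and 10 splits are too few for a share under 0.05.

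Whether the 100 genes with the smallest p in each direction reflect genes or single probes stays open. Among those lower, 23 other probes of 22 genes had a median log2 change of -0.19 (95% bootstrap interval -0.45 to -0.06), where the genes' own probes had -0.62. Among those higher, 22 other probes of 17 genes had 0.30 (-0.12 to 0.45), where their own probes had 0.67. Of these other probes, 20 of the 23 and 15 of the 22 went the same way as the group of genes. The genes were picked for a small p on their own probe, and that choice alone can leave smaller changes on other probes. Signals of single probes, from cross-hybridisation or a splice form, could make up part of these changes, but the values cannot tell this from the choice of genes. Other splits of the arrays gave at most 518 probes at an unadjusted p under 0.05, against 1759 in the real split, which was the 1 of 10 with as many; all 10 splits gave 0 probes after adjustment, and 10 splits are too few for a share under 0.05.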
